A study of Danio rerio with 24 samples.

How the data were processed

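Total RNA from the caudal fin of zebrafish was labelled with biotin, per the labels from 6 ug, and hybridised to 24 Affymetrix zebrafish arrays, 3 for each of 4 times in control and in metabolic memory fish. The deposited values are log2 signals per probe set that the authors made with GCRMA in Partek, per the submitters' processing notes. GCRMA corrects background with the probe sequence, normalises between arrays and summarises probes. No versions of these tools are given in the sources used here. Groups were taken from the labels of each sample. The labels name 15 fins and a triplicate for each time. Whether 15 counts the fins of a sample or of a group, and whether the 3 samples of a group came from different fish or from a common pool, is not given in the sources used here. If they share fish, the p values measure only the spread between these samples. The times of day are not given either.

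Of 15617 probe sets, 115 array controls were left out. Probe sets with a log2 value of at least 4 on at least 3 arrays, whatever their group, were tested, which kept 10140 and left out 5362. Gene symbols came from the platform annotation, updated or matched through the gene number for 10711 probe sets, and 7594 tested probe sets carried 1 symbol. They stand for 6451 genes, of which 918 had over 1 probe set and were represented by the probe set with the highest mean. Probe sets with several symbols or none were tested but not named.

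A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with eBayes moderation and no intensity trend. The 14 comparisons were each time against 0 h in each arm, memory against control at each time, the difference of the memory effect at each later time from that at 0 h, and memory against control averaged over the 4 times. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. Named genes were chosen by a rule fixed before the data were examined, together with the gene lists, the comparisons and the alternatives named here. For each comparison the rule takes, among called probe sets with 1 symbol whose 3 arrays in a group lie beyond all 3 of the other, the 10 largest rises and the 10 largest falls, without clone or locus identifiers. For comparisons by time or averaged, the adjusted p alone was asked. The rule adds up to 4 called members of each gene list by size of change and any member of the lists of blastema and wound epidermis, DNA methylation and circadian clock genes, and a gene that passes in a comparison may be followed in the others. The rule allows more genes than are named, and which of them are named was settled after the alternatives had been run, mostly in favour of genes that kept their call.

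The 31 gene lists were blastema and wound epidermis, Wnt pathway, Fgf pathway, Bmp and Tgf-beta pathway, Hedgehog, Notch and retinoic acid pathways, homeobox and patterning factors, injury-induced transcription and stress factors, extracellular matrix remodelling, fibrillar collagen, bone and osteoblast, DNA replication, mitosis, ribosome biogenesis, and protein folding and ER stress. Further lists were neutrophil and macrophage, complement, interferon and antigen presentation, lymphocyte, epidermis and keratinocyte, and pigment cell. The last were skeletal muscle, blood and erythrocyte, endothelium and vessel, nerve and Schwann cell, lateral line and sensory, glycolysis and hypoxia, glucose, insulin and fatty acid metabolism, mitochondrial respiration, antioxidant, DNA methylation and chromatin, p53 and DNA damage, circadian clock, and proteasome. Some genes sit on more than 1 list, such as 20 of the 39 measured injury-induced factors. Lists with at least 10 measured genes were tested with camera of limma, which compares a list with all other genes, at a preset correlation between genes of 0.01 and, beside it, at a correlation estimated from the residuals. With an estimated correlation the calls that held were ribosome biogenesis in control fins at 12 and 24 h, in memory fins at 12 and 24 h, between the arms at 48 h and averaged over times, and collagen, bone and osteoblast genes in memory fins at 12 h. A count adjusted over the list alone uses only the list's own p values. Of 131 camera calls at the preset correlation, 59 are given, picked after the alternatives had been run and mostly from those lost under no alternative but the estimated correlation.

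The alternatives were no filter, a filter at a log2 value of 6, eBayes with intensity trend and robust estimation, no moderation, arrays centred on their median, quantile normalisation once more, the replicate number as a block, a fit on only the groups compared, an added 2-fold threshold, the mean of all probe sets of a gene, and leaving out each array in turn. Leaving out an array leaves 2 in its group, with the spread pooled over all groups. The methods were tested on simulated data with the means and spreads of these arrays and 200 changed probe sets. Each probe set was drawn independently of the others. Over the 14 comparisons of 10140 probe sets, from 67.2% (memory by time at 24 h) to 100% of simulated log2 changes of 1 were called, and from 8.96% (memory by time at 48 h) to 88.1% (averaged over times) of changes of 0.5. The real comparisons called from 2.50% to 69.9% of the probe sets. The adjusted p depends on the share that changes, so the simulated shares do not give the detection in the real comparisons. Figures were drawn with matplotlib 3.10.9.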

Results

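RNA from the caudal fin of zebrafish (Danio rerio), an appendage that regrows after amputation, was measured on 24 Affymetrix zebrafish arrays. The arrays form 8 groups of 3, taken from control fish and from metabolic memory fish at 0, 12, 24 and 48 h after amputation. Memory fish had been injected with 350 mg/kg streptozocin, a toxin of the insulin-producing beta cells, and were then kept for 60 days without the drug. One description calls the control fish untreated and another says that they received citrate buffer. Metabolic memory is the name for changes that outlast a past period of high blood glucose. Arrays of the same group correlated at 0.978 to 0.996, and the lowest correlation over all pairs of arrays was 0.835. On the first principal component, with 58.2% of the variance, the group means were -86.3 for control and -79.2 for memory fins at 0 h, and 12.6 to 34.9 for all later groups. The second component, with 22.8%, ran from 24.2 for control and 49.8 for memory fins at 12 h to -46.6 and -44.4 at 48 h. The array controls for hybridisation had log2 group means of 10.12 to 10.18 at 0 and 12 h and of 9.69 to 9.82 at 24 and 48 h. Whether these sets of arrays were run apart is not given in the sources used here. In the 24 and 48 h comparisons with 0 h, such a difference between arrays cannot be told apart from time. For arrays, their number limits the precision. Changes are log2 differences ± standard error between groups of 3 arrays, from limma's moderated test over 10140 probe sets, with Benjamini-Hochberg adjusted p values.

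**Figure D1:**
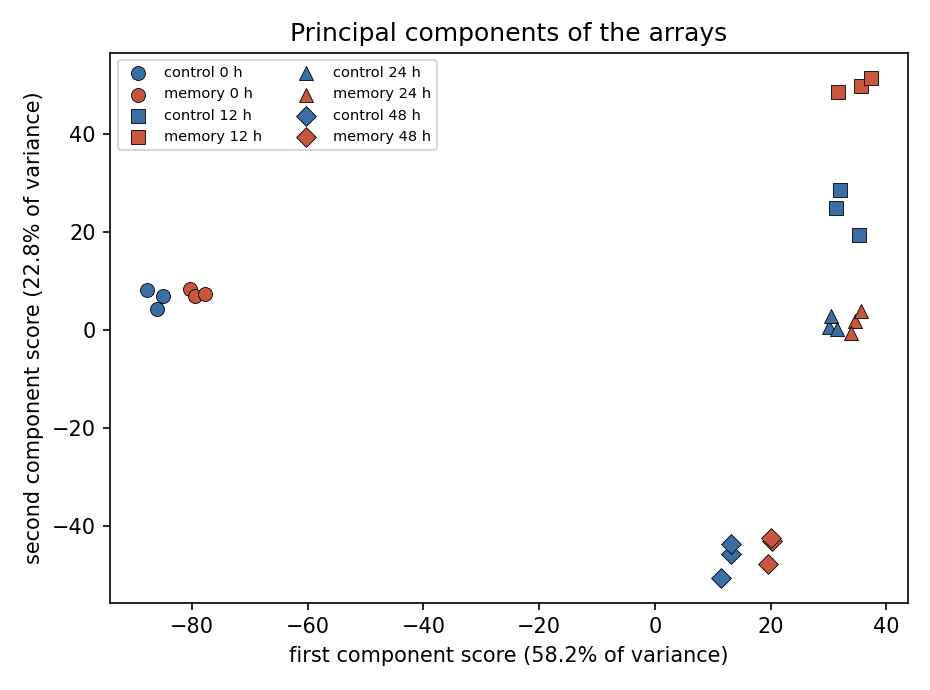
First and second principal components (scores, no unit) of the 24 arrays from the log2 values of the probe sets tested, one point per array, by arm and hours after amputation. The first component holds 58.2% of the variance and parts the 0 h arrays from all others, and memory fins at 12 h had the highest group mean on the second component, 49.8.

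Control fins at 12 h were compared with control fins at 0 h to follow the response of the fin to amputation. The 12 h fins had far more transcript of jac4 (8.34 ± 0.36), of tph1b, an enzyme of serotonin synthesis (6.58 ± 0.15), and of serpinh1b, a chaperone of collagen (6.06 ± 0.37). The chaperone gene hsp90aa1.2 rose by 6.05 ± 0.29 and the coagulation factor gene f5 by 6.03 ± 0.29. Transcript of the keratin gene krt1-19e fell by 7.30 ± 0.21, hgd of tyrosine breakdown fell by 7.17 ± 0.25, and cyp1a, a cytochrome P450 of xenobiotic metabolism, fell by 6.81 ± 0.18. Of these genes the largest adjusted p was 8.85e-12, and all 3 arrays at 12 h lay beyond all 3 at 0 h. In all, 3654 probe sets were called higher and 3293 lower.

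In several lists more members were higher than lower in control fins at 12 h. Ribosome biogenesis genes had 65 higher, 3 lower and 2 not called of 70 (65 higher and 4 lower adjusted over the list alone, camera adjusted p = 2.99e-12, and adjusted p = 0.0254 with an estimated correlation). Members included noc4l of small subunit assembly at 3.55 ± 0.10 and nucleophosmin npm1a at 2.79 ± 0.08. DNA replication genes had 41 higher, 2 lower and 8 not called of 51 (41 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.36e-06, and adjusted p = 0.181 with an estimated correlation). Members included mcm2, a subunit of the replicative helicase, at 3.47 ± 0.19. Protein folding genes had 37 higher, 5 lower and 8 not called of 50 (38 higher and 7 lower adjusted over the list alone, camera adjusted p = 7.86e-06, and adjusted p = 0.0538 with an estimated correlation). Members included the mitochondrial chaperonin hspd1 (4.24 ± 0.09). Mitochondrial respiration genes had 68 higher, 1 lower and 7 not called of 76 (69 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.12e-10, and adjusted p = 0.139 with an estimated correlation). Proteasome genes had 38 higher, 2 lower and 2 not called of 42 (39 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.07e-07, and adjusted p = 0.181 with an estimated correlation).

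In lists of bone, patterning, complement and pigment cell genes more members were lower than higher at 12 h. Genes of fibrillar collagen, bone and osteoblasts had 20 lower, 2 higher and 3 not called of 25 (20 lower and 3 higher adjusted over the list alone, camera adjusted p = 1.04e-06, and adjusted p = 0.0538 with an estimated correlation). Members included ifitm5, made in osteoblasts, at -6.44 ± 0.28 and the collagen X gene col10a1a at -4.96 ± 0.19. Homeobox and patterning factors had 19 lower, 6 higher and 7 not called of 32 (20 lower and 6 higher adjusted over the list alone, camera adjusted p = 0.00171, and adjusted p = 0.181 with an estimated correlation). Genes of complement, interferon and antigen presentation had 14 lower, 2 higher and 10 not called of 26 (14 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00189, and adjusted p = 0.214 with an estimated correlation). Members included cd74a, the invariant chain of MHC class II (-2.05 ± 0.10). Pigment cell genes had 9 lower, 2 higher and 1 not called of 12 (10 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00338, and adjusted p = 0.0842 with an estimated correlation). Members included the neural crest factor sox10 at -2.04 ± 0.14. Bmp and Tgf-beta pathway genes had 12 lower, 5 higher and 11 not called of 28 (12 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.0250, and adjusted p = 0.181 with an estimated correlation). Members included the ligand bmp4 at -3.36 ± 0.15.

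Further lists had members called in both directions at 12 h, with more of them lower. Neutrophil and macrophage genes had 15 lower, 12 higher and 7 not called of 34 (15 lower and 12 higher adjusted over the list alone, camera adjusted p = 0.136). Nerve and Schwann cell genes had 6 lower, 3 higher and 4 not called of 13 (6 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.136). Members included gap43 of growing axons at 4.83 ± 0.23 and myelin basic protein mbpa at -3.91 ± 0.19. Endothelium and vessel genes had 9 lower, 4 higher and 2 not called of 15 (9 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.0289, and adjusted p = 0.153 with an estimated correlation). Members included smooth muscle actin acta2 (-3.28 ± 0.13). Genes of the Hedgehog, Notch and retinoic acid pathways had 16 lower, 5 higher and 6 not called of 27 (16 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.0211, and adjusted p = 0.115 with an estimated correlation). Members included retinol binding protein rbp4 at -4.75 ± 0.18 and aldh1a2, which makes retinoic acid, at 2.35 ± 0.14. Mitosis genes had 21 lower, 10 higher and 24 not called of 55 (21 lower and 10 higher adjusted over the list alone, camera adjusted p = 0.0455, and adjusted p = 0.495 with an estimated correlation). Their camera call was lost without control 0 h replicate 1 (adjusted p = 0.0768) or replicate 3 (0.0679), without control 12 h replicate 1 (0.0664) or replicate 2 (0.0864), with no filter (0.0786), with the stricter filter (0.0574) and with quantile normalisation once more (0.0690). Wnt pathway genes had 9 lower, 5 higher and 7 not called of 21 (9 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.0605). Camera called this list lower with the stricter filter (adjusted p = 0.0201) and without control 12 h replicate 2 (adjusted p = 0.0486). Members included wnt11 at -4.70 ± 0.18. Circadian clock genes had 15 lower, 8 higher and 4 not called of 27 (15 lower and 8 higher adjusted over the list alone, camera adjusted p = 0.0239, and adjusted p = 0.220 with an estimated correlation). Members included the cryptochrome gene cry3b at -5.22 ± 0.09, bmal1a of the core clock at -2.67 ± 0.12 and the clock repressor gene ciarta at 2.91 ± 0.25. Camera lost its calls here with the stricter filter for the Hedgehog list (adjusted p = 0.104) and the clock list (adjusted p = 0.0666), and without control 12 h replicate 1 for the endothelium list (adjusted p = 0.0505).

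At 24 h after amputation control fins were compared with the same 0 h fins. The fins still held far more tph1b (7.49 ± 0.15, adjusted p = 3.43e-19) and had gained tncb, tenascin C of the wound matrix (5.27 ± 0.27). Expression of cyp1a (-7.01 ± 0.18) and krt1-19e (-7.16 ± 0.21) stayed below the 0 h level in all 3 arrays. Of the mitosis genes there were 46 higher, 1 lower and 8 not called of 55 (47 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000733, and adjusted p = 0.321 with an estimated correlation). DNA replication genes had 43 higher, 1 lower and 7 not called of 51 (44 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.72e-07, and adjusted p = 0.176 with an estimated correlation). Members included mcm2 at 3.18 ± 0.19. Ribosome biogenesis genes had 64 higher, 3 lower and 3 not called of 70 (64 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.15e-11, and adjusted p = 0.0313 with an estimated correlation). Over all genes, 3729 probe sets were higher and 3207 lower.

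At 48 h control fins were compared with the same 0 h fins. Transcripts of and2, an actinodin of the fibres that shape the fin fold, rose by 4.88 ± 0.23, those of and1 by 3.03 ± 0.20, tncb by 5.26 ± 0.27 and the enamelin gene enam by 5.14 ± 0.31. The actinodin genes had been below the 0 h level at 12 h (and1 -6.36, and2 -4.26). Sonic hedgehog shha rose by 2.41 ± 0.23, aldh1a2 by 3.27 ± 0.14 and the DNA methyltransferase gene dnmt3ba by 2.48 ± 0.16. The lubricin gene prg4a fell by 7.91 ± 0.25, myostatin mstnb fell by 6.07 ± 0.10 and lysozyme lyz fell by 4.07 ± 0.20. The largest adjusted p of these genes at 48 h was 6.8e-09. The blastema and wound epidermis list had 31 higher, 5 lower and 9 not called of 45 (32 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.000306, and adjusted p = 0.219 with an estimated correlation). Genes of fibrillar collagen, bone and osteoblasts, with and1 and and2 among them, had 13 higher, 6 lower and 6 not called of 25 (13 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.395). Mitosis genes had 44 higher and 11 not called of 55 (44 higher adjusted over the list alone, camera adjusted p = 4.29e-05, and adjusted p = 0.284 with an estimated correlation). Epidermis and keratinocyte genes had 30 lower, 10 higher and 9 not called of 49 (31 lower and 10 higher adjusted over the list alone, camera adjusted p = 0.000874, and adjusted p = 0.219 with an estimated correlation). In all, 3800 probe sets were higher and 3292 lower. This balance depends on the scale and the filter: 53.6% of the calls were higher, but 42.7% with no filter and 48.4% with each array centred on its median, where the shares at 12 and 24 h went from 52.6% and 53.8% to 47.5% and 49.8%.

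Memory fins were compared with their own 0 h fins to follow amputation in the memory arm. At 12 h jac4 stood 9.39 ± 0.36 above 0 h, gap43 5.61 ± 0.23 above, and the growth factor gene hbegfb, an activator of the EGF receptor, 5.67 ± 0.18 above. Myostatin mstnb fell by 6.88 ± 0.10, and1 fell by 6.51 ± 0.20 and cry3b fell by 5.38 ± 0.09. Ribosome biogenesis genes had 65 higher, 1 lower and 4 not called of 70 (65 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.42e-15, and adjusted p = 0.00857 with an estimated correlation). Collagen, bone and osteoblast genes had 21 lower, 2 higher and 2 not called of 25 (21 lower and 2 higher adjusted over the list alone, camera adjusted p = 1.73e-07, and adjusted p = 0.0306 with an estimated correlation). Mitosis genes had 33 lower, 6 higher and 16 not called of 55 (33 lower and 6 higher adjusted over the list alone, camera adjusted p = 0.00107, and adjusted p = 0.366 with an estimated correlation). At 12 h 3613 probe sets were higher than at 0 h and 3447 lower.

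At 24 h memory fins had 3722 probe sets higher and 3199 lower than at 0 h, and at 48 h 3833 and 3247. At 24 h jac4 was at 8.27 ± 0.36, acp5a of bone-resorbing cells at 4.81 ± 0.27 and ciarta at 4.25 ± 0.25. By 48 h and2 had risen by 5.35 ± 0.23, enam by 5.80 ± 0.31 and tph1b by 6.38 ± 0.15, and prg4a fell by 7.88 ± 0.25 and lyz fell by 5.07 ± 0.20. Mitosis genes at 24 h had 45 higher and 10 not called of 55 (45 higher adjusted over the list alone, camera adjusted p = 0.000109, and adjusted p = 0.272 with an estimated correlation). At 48 h the mitosis list had 47 higher and 8 not called of 55 (47 higher adjusted over the list alone, camera adjusted p = 2.28e-06, and adjusted p = 0.216 with an estimated correlation). Injury-induced transcription and stress factors had 18 lower, 8 higher and 13 not called of 39 (18 lower and 8 higher adjusted over the list alone, camera adjusted p = 0.00975, and adjusted p = 0.405 with an estimated correlation) at 48 h. In control fins at 48 h this list had 16 higher, 14 lower and 9 not called of 39 (16 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.559), and the extracellular matrix remodelling list 23 higher, 4 lower and 11 not called of 38 (23 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0660). Camera called the matrix list higher there with no filter (adjusted p = 0.0122) and with only the groups compared (adjusted p = 0.0315). Extracellular matrix remodelling genes had 24 higher, 5 lower and 9 not called of 38 (24 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0363, and adjusted p = 0.216 with an estimated correlation) at 48 h. This camera call was lost without memory 0 h replicate 3 (adjusted p = 0.0514), with the stricter filter (adjusted p = 0.0592) and with the mean of all probe sets of a gene (adjusted p = 0.0605).

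The responses of the arms ran close to each other. Over 10140 probe sets, which are not independent replicates, the change from 0 h in control fins correlated with that in memory fins at r = 0.902 at 12 h, 0.945 at 24 h and 0.931 at 48 h (Spearman correlation 0.861, 0.926 and 0.916). The slope of the memory response on the control response was 0.902, 0.930 and 0.920. A slope equals the correlation where both responses spread alike, so these values near r do not show a smaller response in memory fins. Both arms called 2878 probe sets higher and 2643 lower at 12 h, where independent calls would share 1302 and 1119, and called 157 in opposite directions. Opposite calls numbered 21 at 24 h and 31 at 48 h.

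**Figure D2:**
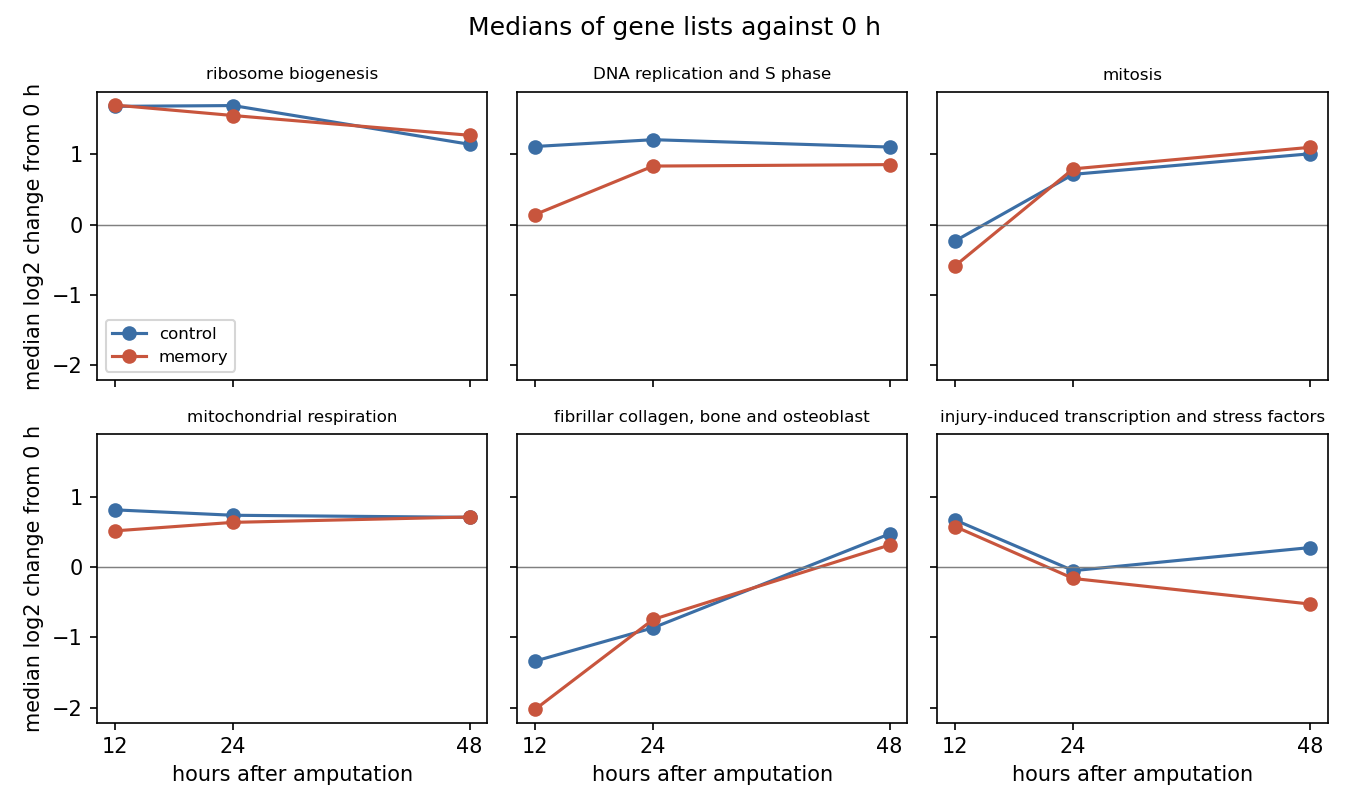
Median log2 change from 0 h (no unit) of 6 gene lists at 12, 24 and 48 h after amputation, with a line for control fins and one for memory fins. At 12 h the median of the DNA replication list was 1.11 in control and 0.14 in memory fins.

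Memory and control fins were compared at 0 h to see how they differed before amputation. Memory fins had more transcript of mcm2 (1.46 ± 0.19, adjusted p = 0.000101) and mcm5 (1.00 ± 0.12), subunits of the replicative helicase, and of odc1, the first enzyme of polyamine synthesis (1.41 ± 0.25). Of the chaperone genes, the mitochondrial hspd1 was at 0.79 ± 0.09, and the endoplasmic reticulum chaperones hsp90b1 and hspa5 at 0.74 ± 0.11 and 0.74 ± 0.14. The cilium transcription factor gene rfx2 rose by 1.81 ± 0.41 and bxdc2 of ribosome assembly by 1.37 ± 0.21. The nucleoside kinase gene uck2a fell by 1.39 ± 0.16 and the zinc finger factor gene zbtb16a fell by 1.12 ± 0.24. Myeloperoxidase mpx of neutrophils was 1.56 ± 0.26 higher and lyz 1.17 ± 0.20 higher. DNA replication genes had 12 higher and 39 not called of 51 (15 higher adjusted over the list alone, camera adjusted p = 0.000148, and adjusted p = 0.546 with an estimated correlation). Protein folding genes had 8 higher and 42 not called of 50 (10 higher adjusted over the list alone, camera adjusted p = 0.000148, and adjusted p = 0.339 with an estimated correlation), and proteasome genes 4 higher and 38 not called of 42 (5 higher adjusted over the list alone, camera adjusted p = 4.12e-05, and adjusted p = 0.546 with an estimated correlation). Mitosis genes had 4 lower and 51 not called of 55 (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.09e-06, and adjusted p = 0.546 with an estimated correlation). The neutrophil and macrophage list had 4 higher and 30 not called of 34 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0159, and adjusted p = 0.424 with an estimated correlation). Its camera call was lost without control 0 h replicate 1 (adjusted p = 0.0850) and with the stricter filter (adjusted p = 0.210).

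At 0 h, 367 probe sets were higher in memory fins and 193 lower, of which 41 changed at least 2-fold. In 23.4% of all probe sets the 3 memory and 3 control arrays did not overlap, where chance gives 10%. With each array centred on its median, 52.3% of the calls were higher, against 65.5%. With the spread estimated from these 6 arrays alone, 81 probe sets were called, and mpx (adjusted p = 0.0717) and lyz (adjusted p = 0.0864) were not among them. Of the 71 called genes that the naming rule gives at 0 h, 58 lost their call under at least 1 alternative, and the genes named above were picked mostly from those that kept it.

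Memory and control fins at 12 h were compared to see how they differed early in regeneration. Memory fins had more transcript of several genes, with the collagenase mmp13a at 3.06 ± 0.30, the gelatinase mmp9 at 1.50 ± 0.13, annexin anxa2b at 3.42 ± 0.22, and nrg1, a ligand of ErbB receptors, at 2.24 ± 0.49. The collagen chaperone gene serpinh1b fell by 2.66 ± 0.37, the stress kinase gene map2k6 fell by 2.36 ± 0.14, and tfam, which keeps mitochondrial DNA, fell by 1.11 ± 0.14. Of these genes the largest adjusted p was 0.00130, and all 3 arrays of each arm lay beyond those of the other. The extracellular matrix remodelling list, to which mmp13a and mmp9 belong, had 8 lower, 7 higher and 23 not called of 38 (8 lower and 7 higher adjusted over the list alone, camera adjusted p = 0.545). In memory fins DNA replication genes had 35 lower and 16 not called of 51 (37 lower adjusted over the list alone, camera adjusted p = 3.26e-10, and adjusted p = 0.165 with an estimated correlation). Members included the clamp loader gene rfc1 (-1.62 ± 0.13) and pola2 of DNA polymerase alpha (-1.31 ± 0.19). The mitosis list had 41 lower and 14 not called of 55 (42 lower adjusted over the list alone, camera adjusted p = 3.09e-08, and adjusted p = 0.226 with an estimated correlation). Members included cdca8 of the chromosomal passenger complex (-1.37 ± 0.20) and cyclin ccna2 (-1.21 ± 0.19). Mitochondrial respiration genes had 30 lower, 3 higher and 43 not called of 76 (30 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.693 with an estimated correlation). The camera call of respiration was lost without control 12 h replicate 3 (adjusted p = 0.154), without memory 12 h replicate 1 (adjusted p = 0.0701) and with each array centred on its median (adjusted p = 0.0607). Ribosome biogenesis genes had 22 higher, 2 lower and 46 not called of 70 (22 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.37e-05, and adjusted p = 0.165 with an estimated correlation). Members included bxdc2 at 1.01 ± 0.21.

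Further lists were compared between the arms at 12 h. Epidermis and keratinocyte genes had 17 higher, 3 lower and 29 not called of 49 (17 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00272, and adjusted p = 0.277 with an estimated correlation). Members included krt1-19e at 2.12 ± 0.21 and itga6b, an integrin of basal keratinocytes, at 1.30 ± 0.25. Neutrophil and macrophage genes had 10 higher, 2 lower and 22 not called of 34 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000225, and adjusted p = 0.0960 with an estimated correlation). Genes of glycolysis and hypoxia had 13 higher, 5 lower and 17 not called of 35 (13 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.218 with an estimated correlation). Members included the hypoxia-responsive ndrg1a at 2.32 ± 0.17, phosphofructokinase pfkpa at 1.36 ± 0.16 and the mitophagy receptor bnip3 at -1.54 ± 0.14. Genes of glucose, insulin and fatty acid metabolism had 13 lower, 8 higher and 20 not called of 41 (14 lower and 11 higher adjusted over the list alone, camera adjusted p = 0.861). Members included hmgcs1 of cholesterol synthesis at 1.72 ± 0.20 and the growth factor igf2a at 1.66 ± 0.25. Antioxidant genes had 18 lower, 8 higher and 15 not called of 41 (18 lower and 9 higher adjusted over the list alone, camera adjusted p = 0.343). Fgf pathway genes had 5 lower, 2 higher and 10 not called of 17 (5 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.541). Members included the Fgf target etv4 at -1.56 ± 0.11 and the receptor fgfr3 at -1.47 ± 0.27. Collagen, bone and osteoblast genes had 12 lower and 13 not called of 25 (12 lower adjusted over the list alone, camera adjusted p = 0.0398, and adjusted p = 0.363 with an estimated correlation). Members included msx2b, a factor of osteoblasts and blastema, at -1.38 ± 0.30 and acp5a at -1.12 ± 0.27. DNA methylation, demethylation and chromatin genes had 19 lower, 4 higher and 29 not called of 52 (20 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.176). Members included dnmt3ba at -0.92 ± 0.16, uhrf1, which guides maintenance methylation, at -0.62 ± 0.14, the methyl-binding mbd3b at -1.83 ± 0.19 and gadd45aa of DNA demethylation and repair at 1.14 ± 0.21. Clock genes had 9 higher, 1 lower and 17 not called of 27 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.352 with an estimated correlation). Members included the light-induced clock gene per2 at 1.28 ± 0.28 and nfil3-6 at 1.40 ± 0.30. The camera call of clock genes was lost without control 12 h replicate 1 (adjusted p = 0.0510) or memory 12 h replicate 3 (adjusted p = 0.0710). That of collagen, bone and osteoblast genes was lost without control 12 h replicate 3 (adjusted p = 0.247), memory 12 h replicate 2 (adjusted p = 0.0590) or memory 12 h replicate 3 (adjusted p = 0.0710), with only the groups compared (adjusted p = 0.0648) and, just at the limit of 0.05, with the replicate block. Camera made no call for the glucose, antioxidant, Fgf and DNA methylation lists, but with no filter it called the DNA methylation list lower (adjusted p = 0.0299).

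At 12 h, 1569 probe sets were higher in memory fins and 2097 lower, 626 of them at least 2-fold, and the arms did not overlap in 42.8% of all probe sets, where chance gives 10%. The poly-A control transcripts added to the RNA averaged 5.36 ± 0.06 in memory and 5.07 ± 0.05 in control fins at 12 h (SD, n = 3, log2). In memory fins at 0 h they averaged 5.25 ± 0.12, with 5.33 and 5.30 in replicates 1 and 3. With each array centred on its median, 53.3% of the calls were higher, against 42.8%. With the spread estimated from these 6 arrays alone, 2192 probe sets were called, and per2 (adjusted p = 0.0651) was not among them. Of the 147 called genes that the naming rule gives at 12 h, 41 lost their call under at least 1 alternative, and the genes named above were picked mostly from those that kept it.

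**Figure D3:**
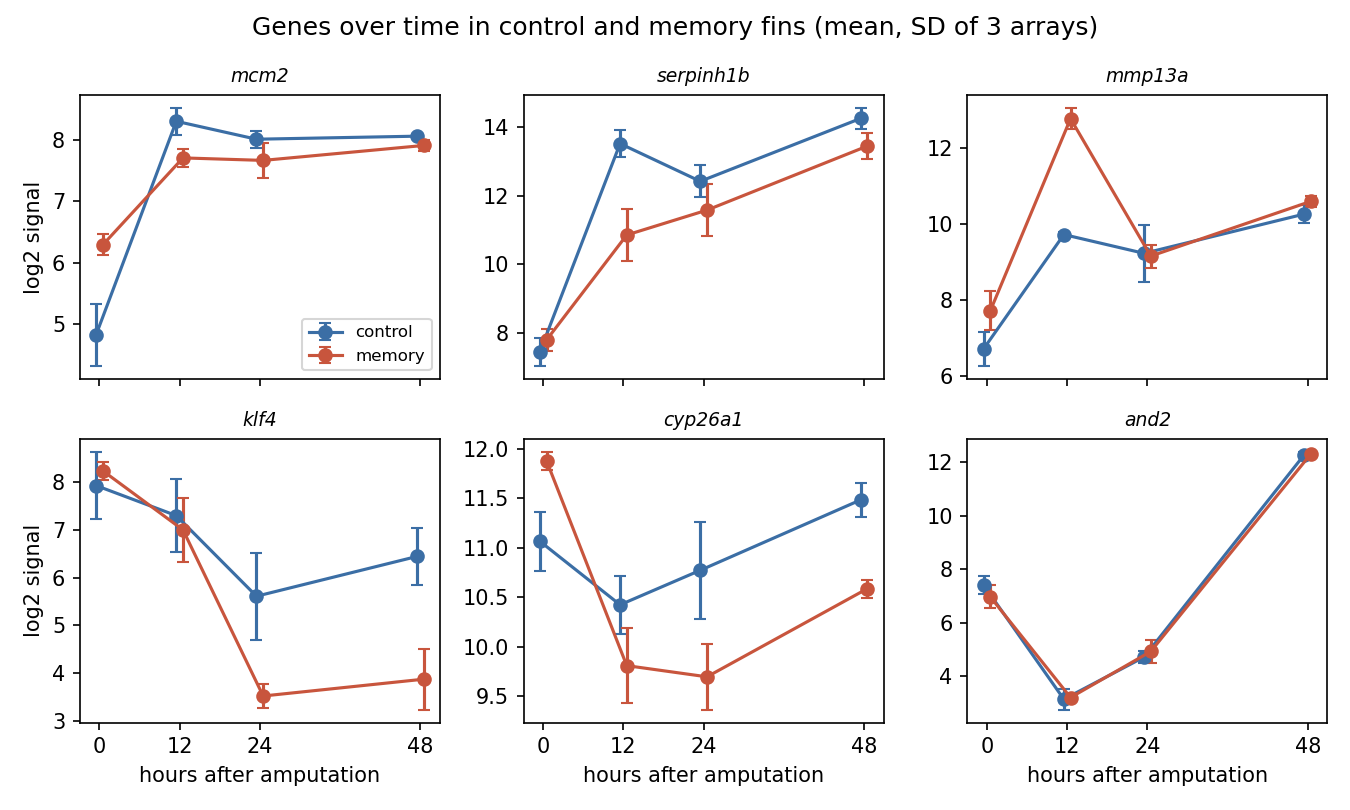
Mean log2 signal of 6 genes against hours after amputation in control and memory fins, with bars of 1 SD over 3 arrays. At 12 h mmp13a averaged 9.73 ± 0.08 in control and 12.78 ± 0.28 in memory fins, and serpinh1b averaged 13.51 ± 0.40 and 10.85 ± 0.75.

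At 24 h the arms were closer to each other. Memory fins had less irg1l, a relative of the itaconate-making enzyme of immune cells (-4.62 ± 0.81, adjusted p = 0.00535), less of the fatty acid elongase gene elovl6l (-1.37 ± 0.23), and less grhl1, an epidermal transcription factor (-0.77 ± 0.13). They had more of the keratin gene krt17 (0.76 ± 0.12) and of enolase eno1b (0.75 ± 0.13). Genes of glycolysis and hypoxia had 4 higher, 1 lower and 30 not called of 35 (15 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000144, and adjusted p = 0.125 with an estimated correlation), and bnip3 of this list was at -0.89 ± 0.14. DNA replication genes had 1 lower and 50 not called of 51 (4 lower adjusted over the list alone, camera adjusted p = 2.45e-06, and adjusted p = 0.418 with an estimated correlation), with a median change of -0.26.

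At 24 h, 150 probe sets were higher in memory fins and 193 lower, and 1849 had an unadjusted p under 0.05. The arms did not overlap in 28.9% of all probe sets, where chance gives 10%. The count rests on single arrays: it was 43 without control 24 h replicate 1, 52 without control 24 h replicate 2, 530 without control 24 h replicate 3, 92 without memory 24 h replicate 2 and 55 without memory 24 h replicate 3. With the spread estimated from these 6 arrays alone it was 198, and bnip3 was not called (adjusted p = 0.0540). Of the 56 called genes that the naming rule gives at 24 h, 50 lost their call under at least 1 alternative, and the genes named above were picked mostly from those that kept it.

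At 48 h memory fins were compared with control fins late in the series. The matrix signal gene ccn1 was at -2.57 ± 0.40 (adjusted p = 0.00128), the transcription factor genes klf4 and klf2a at -2.57 ± 0.46 and -2.17 ± 0.26, id2b, an inhibitor of differentiation factors, at -2.13 ± 0.34, and the growth arrest gene btg2 at -2.13 ± 0.42. Of these, klf4, klf2a and btg2 are on the list of injury-induced factors. The vessel signal gene angpt2b was at -0.74 ± 0.14 and wnt11 at -1.19 ± 0.18. Higher in memory fins were fosl1b of the AP-1 family (1.41 ± 0.15), zbtb16a (1.27 ± 0.24) and dyskerin dkc1 of ribosome assembly (0.59 ± 0.12). Injury-induced factors had 15 lower and 24 not called of 39 (18 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.66e-11, and adjusted p = 0.144 with an estimated correlation). The mean signal of this list over arrays was 9.30 ± 0.32 in control fins, from 9.01 to 9.64, and 8.51 ± 0.10 in memory fins (SD, n = 3). By replicate number it fell in control fins (9.64, 9.24 and 9.01) and on through memory fins (8.62, 8.50 and 8.42). An order of the samples therefore cannot be told apart from the arm here. At 24 h it fell in control fins (9.19, 9.07 and 8.77) but rose in memory fins (8.63, 8.70 and 8.80). Ribosome biogenesis genes had 9 higher and 61 not called of 70 (20 higher adjusted over the list alone, camera adjusted p = 1.14e-12, and adjusted p = 0.0220 with an estimated correlation). Glycolysis and hypoxia genes had 7 higher, 2 lower and 26 not called of 35 (12 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00623, and adjusted p = 0.144 with an estimated correlation). Genes of p53 and DNA damage had 5 lower and 30 not called of 35 (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0170, and adjusted p = 0.144 with an estimated correlation). Members included the cyclin gene ccng2 (-1.70 ± 0.22).

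At 48 h, 279 probe sets were higher in memory fins and 298 lower, and the arms did not overlap in 31.3% of all probe sets, where chance gives 10%. With no filter 51.8% of the calls were higher and with the stricter filter 51.2%, against 48.4%. The count was 185 without control 48 h replicate 1, 226 without control 48 h replicate 2, 178 without memory 48 h replicate 2 and 270 without memory 48 h replicate 3. Of the 72 called genes that the naming rule gives at 48 h, 57 lost their call under at least 1 alternative, and the genes named above were picked mostly from those that kept it.

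**Figure D4:**
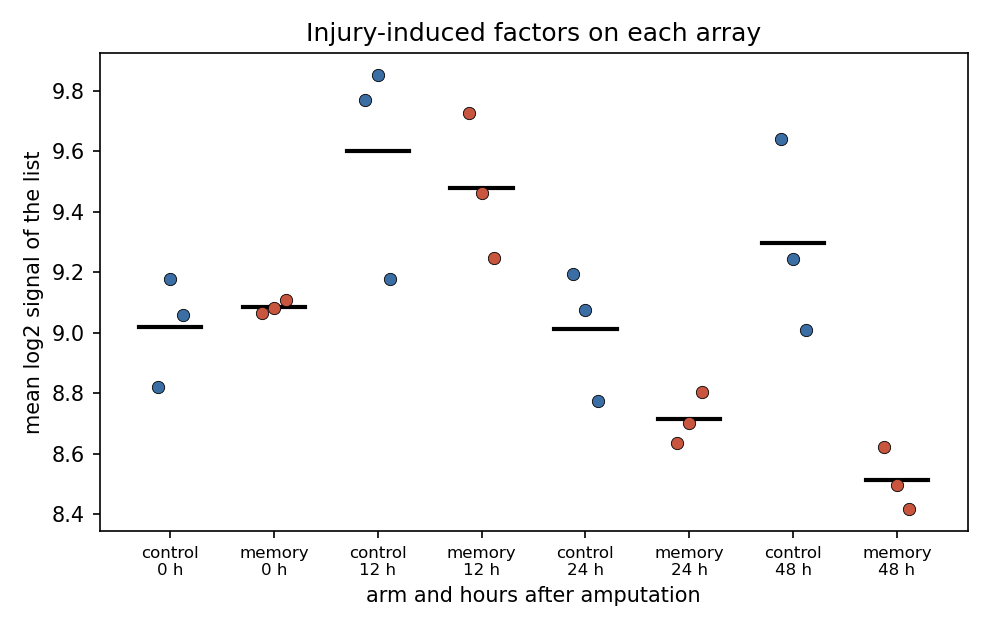
Mean log2 signal of the 39 measured injury-induced factors on each array, one point per array with the group mean as a bar, by arm and hours after amputation. Control fins at 48 h spread from 9.01 to 9.64, all above the highest memory array at 48 h, 8.62. In each arm at 48 h the values fell in order of replicate number.

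The memory response was set against the control response by testing whether the memory effect at each later time differed from that at 0 h. At 12 h serpinh1b responded less in memory fins (difference of responses -3.00 ± 0.53, adjusted p = 0.000439), as did mcm2 (-2.06 ± 0.26), pola2 (-1.90 ± 0.27) and hspd1 (-1.33 ± 0.13). The annexin gene anxa2b responded more (3.51 ± 0.30), as did mmp13a (2.05 ± 0.42) and gadd45aa (1.67 ± 0.30). At 0 h mcm2 (1.46 ± 0.19) and hspd1 (0.79 ± 0.09) were already higher in memory fins, which carries much of their values, and at 12 h itself they were at -0.60 ± 0.19 and -0.54 ± 0.09. The 12 h call of mcm2 was lost without control 12 h replicate 3 (adjusted p = 0.0748) or memory 12 h replicate 2 (adjusted p = 0.0632). Tested for a smaller or larger response, DNA replication genes had 35 lower and 16 not called of 51 (38 lower adjusted over the list alone, camera adjusted p = 7.85e-14, and adjusted p = 0.153 with an estimated correlation), and respiration genes 28 lower, 1 higher and 47 not called of 76 (31 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000250, and adjusted p = 0.421 with an estimated correlation). Epidermis and keratinocyte genes had 11 higher, 3 lower and 35 not called of 49 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00250, and adjusted p = 0.362 with an estimated correlation). The effect differed from 0 h in 2378 probe sets, 921 higher and 1457 lower. With each array centred on its median, which raises every change by 0.10, 55.8% of the calls were higher, against 38.7%. With the spread estimated from these 12 arrays alone, 1459 were called.

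At 24 h the memory effect differed from that at 0 h in 254 probe sets, and at 48 h in 444. The retinoic acid hydroxylase gene cyp26a1 had a lower effect at 24 h (-1.89 ± 0.32, adjusted p = 0.00540) and at 48 h (-1.71 ± 0.32), as did mcm2 (-1.81 ± 0.26 and -1.61 ± 0.26), mcm5 (-1.42 ± 0.18 and -1.23 ± 0.18) and hspa5 (-0.99 ± 0.20 and -1.06 ± 0.20). Both times are set against the same 0 h arrays, where mcm2, mcm5 and hspa5 were higher in memory fins, and this carries much of their values. The same holds in part for cyp26a1, called higher at 0 h (0.81 ± 0.23) but not without control 0 h replicates 1 or 2 (adjusted p = 0.160 and 0.0559) or memory 0 h replicates 1, 2 or 3 (adjusted p = 0.0968, 0.0603 and 0.0960), and for zbtb16a, lower at 0 h (-1.12 ± 0.24). Between the arms at 24 h there was no call for mcm2 (-0.34 ± 0.19, adjusted p = 0.338), mcm5 (-0.42 ± 0.12, adjusted p = 0.0668) or hspa5 (-0.25 ± 0.14, adjusted p = 0.367), although mcm5 was called with the replicate block (adjusted p = 0.0476), and at 48 h none for mcm2 (-0.15 ± 0.19), mcm5 (-0.23 ± 0.12, adjusted p = 0.302) or hspa5 (-0.33 ± 0.14, adjusted p = 0.185). At 48 h ccn1 (-3.02 ± 0.57), id2b (-2.48 ± 0.48) and the Notch ligand gene jag1a (-2.50 ± 0.54) had lower effects, and the urea transporter gene slc14a2 (3.46 ± 0.73) and zbtb16a (2.39 ± 0.34) had higher effects. At 24 h DNA replication genes had 11 lower and 40 not called of 51 (19 lower and 1 higher adjusted over the list alone, camera adjusted p = 8.49e-11, and adjusted p = 0.167 with an estimated correlation). At 48 h they had 6 lower and 45 not called of 51 (11 lower and 2 higher adjusted over the list alone, camera adjusted p = 4.75e-06, and adjusted p = 0.477 with an estimated correlation). Protein folding genes at 24 h had 4 lower and 46 not called of 50 (11 lower adjusted over the list alone, camera adjusted p = 8.48e-05, and adjusted p = 0.167 with an estimated correlation), and at 48 h 7 lower, 1 higher and 42 not called of 50 (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.41e-05, and adjusted p = 0.157 with an estimated correlation). Injury-induced factors at 48 h had 8 lower and 31 not called of 39 (14 lower adjusted over the list alone, camera adjusted p = 1.85e-06, and adjusted p = 0.477 with an estimated correlation). The 24 h count was 164 without control 0 h replicate 1, 122 without control 24 h replicate 1, 88 without control 24 h replicate 2, 108 without memory 24 h replicate 2 and 89 without memory 24 h replicate 3. The 48 h count was 194 without control 48 h replicate 1, 206 without control 48 h replicate 2, 191 without memory 48 h replicate 2 and 263 without memory 48 h replicate 3. Of the called genes that the naming rule gives by time, 42 of 131 at 12 h, 27 of 39 at 24 h and 38 of 65 at 48 h lost their call under at least 1 alternative, and those named were picked mostly from the others.

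Averaged over the 4 times, memory fins had more hmgcs1 (1.04 ± 0.10, adjusted p = 9.12e-07), mmp13a (1.08 ± 0.15) and gap43 (0.52 ± 0.12) than control fins. They had less irg1l (-2.46 ± 0.40), btg2 (-1.24 ± 0.21), klf4 (-1.16 ± 0.23), grhl1 (-0.68 ± 0.06) and bnip3 (-0.81 ± 0.07). Ribosome biogenesis genes had 42 higher, 1 lower and 27 not called of 70 (47 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.25e-11, and adjusted p = 0.0347 with an estimated correlation). Members included bxdc2 at 0.72 ± 0.11 and the nucleolar protein gene fbl at 0.35 ± 0.05. Mitosis genes had 40 lower, 1 higher and 14 not called of 55 (40 lower and 2 higher adjusted over the list alone, camera adjusted p = 2.42e-10, and adjusted p = 0.202 with an estimated correlation). Members included the spindle gene nusap1 at -0.53 ± 0.08. Neutrophil and macrophage genes had 17 higher, 3 lower and 14 not called of 34 (19 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00133, and adjusted p = 0.0801 with an estimated correlation). Members included mpx at 0.61 ± 0.13. Glycolysis and hypoxia genes had 19 higher, 4 lower and 12 not called of 35 (20 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.000577, and adjusted p = 0.0801 with an estimated correlation). In all 1616 probe sets were higher and 1706 lower, 34 of them at least 2-fold. This balance turned with each array centred on its median (1757 higher and 1600 lower), and narrowly with the stricter filter (1444 and 1423) and quantile normalisation once more (1627 and 1607). Averaged over 0, 24 and 48 h alone, a setting chosen after seeing the data, 1401 were called, 773 higher and 628 lower. The lists with too few measured genes for a list test were lymphocyte (4 of 36 measured), skeletal muscle (6 of 70), blood and erythrocyte (6 of 37) and lateral line and sensory (7 of 19).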

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

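The tests of the order of events at 12 h, of the main axis of spread between arrays and of the clock genes were chosen after the results were seen, and those of dim signal, of handling and of other splits of the arrays before. Memory effects that differed from the effect at 0 h stood out because the difference itself was tested. They numbered 2378 probe sets at 12 h, 254 at 24 h and 444 at 48 h. At 12 h the differences were -3.00 for serpinh1b, -2.06 for mcm2, -1.90 for pola2, -1.33 for hspd1, 3.51 for anxa2b, 2.05 for mmp13a and 1.67 for gadd45aa. At 24 h they were -1.89 for cyp26a1, -1.81 for mcm2, -1.42 for mcm5 and -0.99 for hspa5. At 48 h they were -3.02 for ccn1, -2.50 for jag1a, -2.48 for id2b, -1.71 for cyp26a1, -1.61 for mcm2, -1.23 for mcm5, -1.06 for hspa5, 3.46 for slc14a2 and 2.39 for zbtb16a. All these differences rest on the same 0 h arrays, where mcm2, mcm5, hspa5 and hspd1 were higher in memory fins by 1.46, 1.00, 0.74 and 0.79 and zbtb16a was at -1.12, which carries much of their values. Camera adjusted p at 12 h was 7.85e-14 for DNA replication, 0.000250 for respiration and 0.00250 for epidermis, with adjusted p = 0.153, 0.421 and 0.362 with an estimated correlation. At 24 h it was 8.49e-11 for DNA replication and 8.48e-05 for protein folding, both with adjusted p = 0.167 with an estimated correlation. At 48 h it was 4.75e-06 for DNA replication, 1.85e-06 for injury-induced factors and 1.41e-05 for protein folding, with adjusted p = 0.477, 0.477 and 0.157 with an estimated correlation. Outside the comparisons, the poly-A control transcripts on the memory arrays at 12 h averaged 5.36, each above every control array at 12 h. Memory arrays at 0 h came close to this, with 5.33 and 5.30 in replicates 1 and 3.

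Other splits of the same arrays were counted for each comparison. For 3 arrays against 3 the 10 splits are too few for a share under 0.05, and the real split was the 1 with the most calls in each. Its counts, with the highest other split in brackets, were 6947 (0), 6936 (1) and 7092 (2) for control fins at 12, 24 and 48 h against 0 h, and 7060 (1), 6921 (0) and 7080 (0) for memory fins. For memory against control they were 560 (17) at 0 h, 3666 (129) at 12 h, 343 (1) at 24 h and 577 (3) at 48 h. Every other split mixes the groups compared, so a real difference widens its spread. Low counts in the other splits follow from this where the difference is large. For the comparisons by time and averaged, 1 of 100 drawn splits, the real one, gave as many calls, a share under 0.05. The highest other split in these comparisons called 2036 against 2378 at 12 h, 75 against 254 at 24 h, 168 against 444 at 48 h and 1115 against 3322 averaged over times. These splits also mix the arms. The share speaks to whether the arms can be exchanged, not to whether their difference changes with time. If the samples of a group share fish, it does not cover chance between fish.

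Memory and control fins differed most at 12 h, by 3666 probe sets. Loss of dim signal on the memory arrays is argued against as the whole cause, since 39.1% of the brightest of 4 equal parts of the probe sets were called and 22.9% of the dimmest. These shares cannot exclude it as a part, since dim probe sets may be called less often whatever the cause. The mean of the array medians was lower in memory fins at 12 h (4.83) than in any other group, with control fins at 12 h at 4.95. The main axis of spread between arrays of a group is argued against as the whole cause, since with it removed, and the standard errors from before the removal, 3285 probe sets were called at 12 h and at most 482 at another time. A candidate explanation that stays open is that memory fins were behind control fins in regeneration. Over probe sets the 12 h difference correlated at r = -0.317 with the later change from 24 to 48 h in control fins. The correlation was -0.360 to -0.278 with 1 array left out and -0.244 with the main axis removed. In 50 simulations it was -0.0412 to 0.0647, but these drew each probe set independently and without a common order of replicates. Real arrays vary along shared axes, so that range does not bound chance here. Same-number control arrays at 12 h also correlated with those at 24 and 48 h, so the correlation cannot decide the question. A difference in RNA handling that goes with the poly-A controls, and a difference in the time of amputation or sampling, were not tested and stay open.

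Of 39 injury-induced factors, 15 were called lower in memory fins at 48 h and 24 were not called, with a list median of -0.69 and a camera adjusted p of 1.66e-11, lost at adjusted p = 0.144 with an estimated correlation. Loss of dim signal is argued against for the 15 members called lower by limma, since 0% of them lay in the dimmest of 4 equal parts of the probe sets. The list was bright as a whole, with group means of 8.51 to 9.60, so this speaks to these members only. The main axis of spread between arrays of a group cannot be told apart as the cause, since with it removed the list median went to -0.47, klf4 from -2.57 ± 0.46 to -2.17 ± 0.40, fosab from -2.30 ± 0.55 to -1.50 ± 0.31 and nr4a1 from -2.64 ± 0.56 to -2.08 ± 0.45, and 6 of the 15 stayed called with the standard errors from before the removal, which narrows the spread by construction, while 17 members were called with its own. Handling of the fins between sampling and lysis, which may switch on such factors, cannot be told apart either: the 48 h difference correlated over probe sets at r = -0.386 with the loadings of that axis, but the 12 h difference did so at -0.388, and a planned comparison with random lists was left out because co-regulated genes vary together whatever the cause. An effect of the memory state, the difference the design names, stays open as well and was not tested apart from handling. So does an order of the samples, since at 48 h the list mean fell with the replicate number in both arms.

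Clock genes lay away from their 0 h level at 12, 24 and 48 h alike in both arms. A running clock with all fins amputated at a single time of day would return after a day and is argued against as the whole cause. The median size of the change of 27 clock genes at 24 or 48 h was at least 0.959 of that at 12 h. This ratio puts a number on the pattern that prompted the test, so it is not an independent test. Of all probe sets, 68.3% to 69.9% were called against 0 h at each later time in each arm. No ratio for other genes was set beside that of the clock genes. A running clock on top of the response to amputation is therefore not excluded. Another time of day at 0 h than at all later times cannot be told apart from a response to amputation. The 12 h change in control fins and the 24 h change in memory fins, which share no arrays, correlated over clock genes at r = 0.944, as both would give, and the times of day are not given in the sources used here.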

How the results depend on the processing

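The axis removal and the average without 12 h were chosen after seeing the data. Under no filter, a stricter filter, trend and robust eBayes, no moderation, either rescaling and the replicate block, each of the 14 counts stayed within 1.5 times its value. In no 2 groups compared here did every same-number pair of arrays correlate over 0.1, but in control fins at 12 h every pair did with 24 h (0.150 to 0.226) and 48 h (0.154 to 0.370). On the principal component numbered 3, replicate 1 scored highest in 8 of 8 groups and replicate 3 lowest in 7, where chance gives 2.67, so a common order of the replicates stays open. With the replicate number as a block the memory against control counts were 605, 3735, 481 and 746 at 0, 12, 24 and 48 h. Every group holds each replicate number, so the block cannot remove an order that runs on from control to memory arrays. At 12 and 24 h scores on component 3 fell throughout, from control replicate 1 (30.45 and 11.23) to memory replicate 3 (-14.64 and -18.94). At 0 and 48 h the fall was broken. A 2-fold threshold, which by construction calls fewer, gave 3115, 3049 and 3100 in control and 3140, 2950 and 3011 in memory fins against 0 h, 41, 626, 69 and 119 between the arms, 641, 99 and 165 by time and 34 averaged. With only the groups compared in the fit, which leaves fewer arrays for the spread, counts were 81 at 0 h, 2192 at 12 h, 198 at 24 h and 1459 by time at 12 h. With the axis removed the count at 24 h was 761, but 350 with the standard errors from before the removal, and without 12 h the average gave 1401, and the cause was not tested. Leaving out 1 array gave 6583 to 6793, 6561 to 6646 and 6699 to 6770 in control and 6671 to 6857, 6494 to 6660 and 6675 to 6780 in memory fins at 12, 24 and 48 h against 0 h, 374 to 519, 3044 to 3747, 43 to 530 and 178 to 648 between the arms at 0, 12, 24 and 48 h, 1929 to 2468, 88 to 338 and 191 to 487 by time, and 2824 to 3647 averaged, and the cause was not tested. The correlation of the responses was 0.896 at 12 h and 0.927 at 48 h with no filter, and 0.914, 0.952 and 0.937 at 12, 24 and 48 h with the stricter filter, and the cause was not tested. The genes and list tests in the text were picked with these alternatives in view, so their stability overstates that of the whole. Each gene counted once per comparison, of 1987 calls of genes that the naming rule gives, 395 were lost under at least 1 alternative, 350 of them without 1 array, against 6 of the 150 of them given, or 9 of 153 with genes followed from another comparison, and 0 reversed. Between the arms these were 58 of 71 at 0 h, 41 of 147 at 12 h, 50 of 56 at 24 h and 57 of 72 at 48 h. Of 131 camera calls, 124 were lost with an estimated correlation and 32 under another alternative, and of the 59 given 53 and 9. Signal near background limits dim probe sets, and the filter left out 5362.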

Other observations

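The test of the 0 h fins against the response to amputation was chosen after the result was seen. Of 10140 probe sets, 3712 differed between memory and control fins at 1 time, 599 at 2, 76 at 3 and 2 at all 4. The 2 probe sets belong to cyp26a1, which breaks down retinoic acid. On the probe set with the highest mean it was higher in memory fins at 0 h (0.81 ± 0.23, adjusted p = 0.0390) and lower at 12 h (-0.61 ± 0.23, adjusted p = 0.0389), 24 h (-1.08 ± 0.23, adjusted p = 0.0139) and 48 h (-0.90 ± 0.23, adjusted p = 0.0235). These calls of cyp26a1 lie near the threshold, and leaving out 1 array often ended them, with the change in the same direction. At 0 h the adjusted p was 0.160 without control 0 h replicate 1, 0.0559 without control 0 h replicate 2, 0.0968 without memory 0 h replicate 1, 0.0603 without memory 0 h replicate 2 and 0.0960 without memory 0 h replicate 3. At 12 h it was 0.101 without control 12 h replicate 2, 0.131 without control 12 h replicate 3 and 0.221 without memory 12 h replicate 3, where the change of cyp26a1 went to -0.40. At 24 h it was 0.101 without control 24 h replicate 1, 0.0580 without control 24 h replicate 2 and 0.0678 without memory 24 h replicate 2. At 48 h each array left out ended the call of cyp26a1, with 0.0536, 0.0743 and 0.0671 without control 48 h replicates 1, 2 and 3 and 0.0635, 0.0667 and 0.0702 without memory 48 h replicates 1, 2 and 3. The change itself stayed between -0.80 and -0.98 there. The calls of cyp26a1 were also lost with only the groups compared at 0, 12 and 24 h (adjusted p = 0.0662, 0.0995 and 0.0839), with no moderation at 0, 12 and 48 h (0.0641, 0.0613 and 0.0501), with no filter at 0 and 12 h (0.0570 and 0.0632), with arrays centred on their median at 12 h (0.0635) and with quantile normalisation once more at 0 h (0.0534). Memory effects at 24 and 48 h, which share no arrays, correlated over probe sets at r = 0.548, with 104 probe sets called at both times and 102 of them in the same direction, where chance gives 9.80. The hybridisation controls were lower in all groups at 24 and 48 h (9.69 to 9.82) than at 0 and 12 h (10.12 to 10.18). Whether a difference between these sets of arrays adds to the likeness of 24 and 48 h was not tested. Between 12 and 24 h the correlation was 0.263, with 193 called at both and 169 in the same direction, where chance gives 63.1, and between 12 and 48 h it was 0.330, with 259, 228 and 105. Between 0 and 12 h the correlation was 0.151, between 0 and 24 h it was 0.0623, and between 0 and 48 h it was 0.0389. On the principal component numbered 3 memory fins scored below control fins at 12 h (-6.72 and 24.08), 24 h (-17.85 and -0.98) and 48 h (-11.14 and 14.44). Replicate 1 scored highest on it in 8 of 8 groups. A memory effect common to these times therefore cannot be told apart from a common order of the samples along this component.

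Memory fins at 0 h may already stand part of the way toward the amputated state. Over probe sets the 0 h difference between memory and control fins correlated with the 12 h response averaged over both arms at r = 0.262. With 1 array left out it was 0.222 to 0.280. Simulated unrelated contrasts gave -0.0405 to 0.0440, but these drew each probe set independently and with the same spread in every group. Real arrays vary along shared axes, so that range does not bound chance here. Both contrasts hold the 0 h arrays, whose chance values cancel only if both arms have the same spread. The slope was 0.0604, and 454 of 560 called probe sets (81.1%) went the way of the response, against 58.9% of all tested. A difference in the delay between amputation and lysis of the 0 h fins was not tested and stays open.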
